A study of Mus musculus with 6 samples.

How the data were processed

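RNA was measured by sequencing in bone-marrow-derived dendritic cells of C57BL/6 mice. The 6 libraries fall into 2 genotypes of 3, which the labels number 1 to 3. WT cells carried floxed alleles of Hif2a, the gene for HIF-2α whose official symbol is Epas1, and KO cells also carried a CD11c-Cre transgene. Every culture had received DMOG for 24 h and then α-galactosylceramide for 4 h. KO against WT was therefore the only contrast, and the effect of either treatment was not analysed here. The labels do not say whether the numbered libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical.

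The authors deposited 1 table of raw read counts per gene symbol, with no normalization. Per the submitters' processing notes, the genome build was mm10 and the tools included TopHat2, HISAT2, HISAT, SAMtools, HTSeq and DESeq2, with no version, role or order. The aligner behind the table, its gene annotation, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Total RNA was extracted with Trizol, per the labels' protocols. The kit is not named there, so reads of a gene and of an overlapping gene on the other strand may not have been told apart. The table holds 30587 rows, none of which is 0 in all 6 libraries. In 23 symbols the name is repeated, over 47 rows, and the row with most reads kept the symbol. A further 26 rows carry a date in place of a symbol and were left under that name. Coordinates come from a match of symbols to the GENCODE M21 annotation of the same build, which held 29047 of the rows (95%) and 13045 of those tested (98.5%).

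Total counts ran from 14668641 to 17884160 per library. Rows with enough counts for a test were chosen with filterByExpr at its minimum count of 10, which kept 13249 rows and left out 17338. The tested rows held at least 99.75% of the counts of every library. Counts were scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. The common biological coefficient of variation was 8.48%. The SE of a log2 fold change is its size divided by the square root of F. Normalised values are CPM, the edgeR unit in which counts are divided by library size and TMM factor and brought to a common depth, given as mean ± SD over 3 libraries.

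Before the data were examined, 43 gene lists were written down, along with the design, the alternatives and the rule for named genes. Lists with at least 5 tested members (38 of 43) were tested with camera of limma 3.58.1 on log2 CPM, at a preset correlation between genes of 0.01, and adjusted over the 38 lists. Camera asks whether a list moved differently from the other genes. Each list is also given as its number of called members, over all genes tested and adjusted over the list alone. The rule named Epas1 and Cd36 always. It then named the 10 genes with the highest and the 10 with the lowest log2 fold change, among called genes with a mean log2 CPM of at least 1 and no overlap between genotypes, leaving out predicted genes, pseudogenes and clones. Lastly it named up to 4 called members of each list by lowest p, or the member with the lowest p where none was called. Any gene outside that rule whose values are given was chosen after they were seen, and the text says so.

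Alternatives written beforehand were DESeq2 size factors, scaling to library size only, no low-count filter, at least 10 counts in every library of a group, the Wald test of DESeq2 1.42.0, limma-voom, a robust dispersion estimate, the replicate number as a block, each library left out in turn, a 2-fold minimum, camera with an estimated correlation, and fry. Chosen after seeing the data were a fit without WT 2 and KO 1, the libraries with most rows of a lone read, and a fit with offsets that remove trends of counts with GC content and exon length. The procedure was tested on simulated data, 5 tables of the 13249 tested rows with the means and library sizes of the real samples and 200 genes changed in each. With gene-specific dispersions it called 22% of genes changed 1.25-fold, 57.6% at 1.5-fold, 84.8% at 2-fold and 96.8% at 4-fold, all in the right direction, and 8.29% of its calls were false. With dispersions on the mean trend, 3.68% of calls were false. In the simulated list test, the 1 shifted list of 40 was called along with 1 other list. Counts of no 2 replicates agreed within sampling noise, since the chi-square per degree of freedom was at least 4.1 in every pair.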

Results

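RNA sequencing was used to compare dendritic cells grown from bone marrow of mice with floxed Hif2a alleles (WT, 3 libraries) and of mice in which the CD11c-Cre transgene, active in dendritic cells, recombines those alleles (KO, 3 libraries). The stated purpose was to learn how the transcription factor HIF-2α affects glycolipid priming by dendritic cells. All cultures were incubated for 24 h with dimethyloxalylglycine (DMOG), an inhibitor of the hydroxylases that mark HIF α subunits for degradation. They then received for 4 h the glycolipid α-galactosylceramide, which CD1d presents to invariant natural killer T cells. The deposited values were raw read counts per gene. Total counts were 17041448, 15936832 and 14668641 in WT 1, 2 and 3, and 17884160, 16826800 and 17114200 in KO 1, 2 and 3. The first principal component held 57.9% of the variance and separated the genotypes. WT 2 stood apart in low-level reads, with a read in 25408 rows against 18763 to 22275 in the other libraries. Its reads of olfactory receptor genes were 57.5 CPM, against 26.4 CPM in KO 1 and 9.45 to 13 CPM in the other libraries. WT 2 also differed in an abundant row, CT010467.1, which held 0.659% of its counts against 0.0478% to 0.106% in the other libraries. All fold changes below are KO relative to WT, with ± the SE and n = 3 libraries per genotype unless stated.

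Epas1, the targeted gene encoding HIF-2α (chromosome 17, 86753700 to 86833410, plus strand, mm10), was lower in every KO library than in every WT library. It had 339, 352 and 349 reads in WT and 175, 214 and 198 in KO, which is 22.2 ± 1.94 CPM against 11.3 ± 1.55 CPM (SD, n = 3 each). The log2 fold change was -0.98 ± 0.12, or 1.98-fold lower (edgeR adjusted p = 3.45e-05). Gene-level counts also take in exons outside the floxed part, which the labels do not name, so the residual reads do not measure the share of cells that kept the gene. Hif1a, which encodes the related HIF-1α and was chosen after its values were seen, rose 1.46-fold (log2 fold change 0.55 ± 0.06, edgeR adjusted p = 9.97e-06).

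Loss of Hif2a went with higher expression of interferon-induced genes and lower expression of glycolytic and hypoxia-induced genes. In all, 1826 genes rose and 1586 fell in KO, 25.8% of the 13249 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Most changes were small, and 301 of the genes that rose and 183 of those that fell changed at least 2-fold. The 10 genes with the highest fold change under the naming rule were Ifi213, Ifi208, Ms4a4c, Ifit3, Ifi206, Ifi44, Ifit3b, Tgtp2, Ifit1bl1 and Irf7. They ran from 36.2-fold for Ifi213 (chromosome 1, 173566283 to 173599274, minus strand), a member of the interferon-inducible p200 family, to 19.4-fold for Irf7. The 10 with the lowest were F13a1, Mcam, Gsta3, Colgalt2, Dpys, Vldlr, Bok, Mamdc2, Tnnt2 and Adm. F13a1, encoding the A chain of coagulation factor XIII (chromosome 13, 36867178 to 37050244, minus strand), was 5.67-fold lower at 30.8 ± 0.809 CPM in KO against 175 ± 3.44 CPM in WT (SD). Adm, encoding the vasodilator peptide adrenomedullin, was 3.41-fold lower. Groups did not overlap in 5358 genes, 40.4% of those tested, where chance gives 10%. Scaling to library size only raised the log2 fold change of the median gene by 0.033 and left 62.3% of calls higher, against 53.5%, whereas with the GC and length offset, chosen after seeing the data, 48.2% were higher (1675 higher and 1800 lower). Without KO replicate 3 the calls numbered 1195 higher and 975 lower. Groups of 3 libraries allow no permutation p under 0.10, so the p-values here rest on the model, and as the labels do not say whether the libraries came from separate animals or cultures, they measure the spread between these libraries alone.

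**Figure D1:**
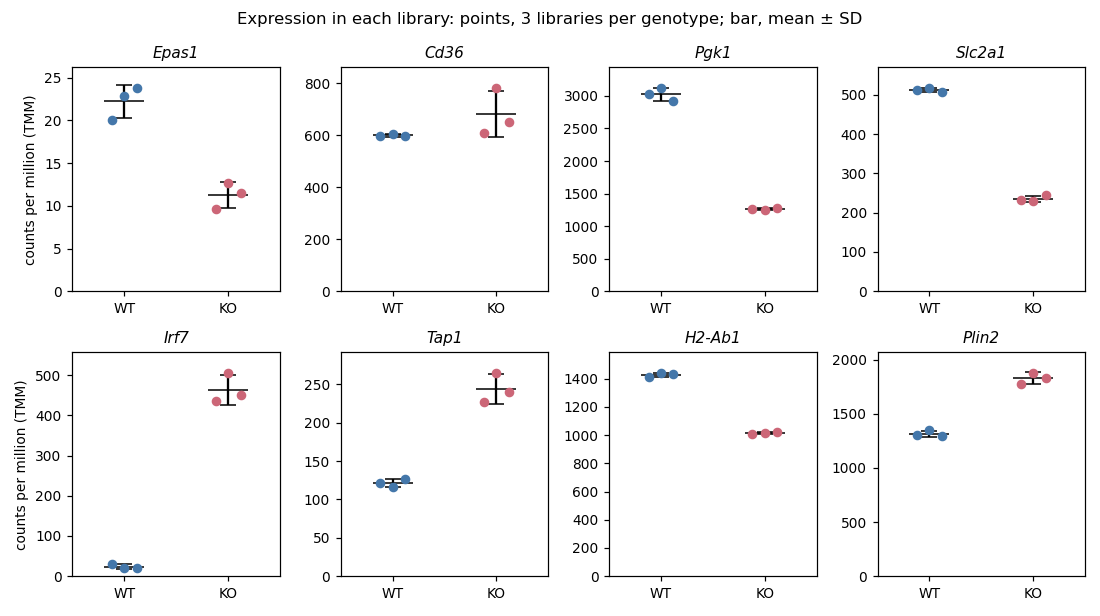
Normalised read counts, as CPM (y axis, starting at 0) of 8 genes in each library; points are the 3 WT (blue) and 3 KO (red) libraries and bars the mean ± SD. Epas1, Pgk1, Slc2a1 and H2-Ab1 lay lower in every KO library than in every WT library, Irf7, Tap1 and Plin2 lay higher, and for Cd36 the KO 2 library at 783 CPM stood above the others.

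Glycolysis genes fell together. Of 22 tested, 18 fell and 2 rose, with the same counts adjusted over the list alone (18 and 2), and the median log2 fold change was -0.72 (camera adjusted p = 1.03e-11; adjusted p = 0.146 with an estimated correlation). Pgk1, encoding phosphoglycerate kinase (chromosome X, 106187100 to 106203699, plus strand), was 2.40-fold lower, from 3027 ± 98.2 to 1263 ± 19.0 CPM (SD; edgeR adjusted p = 3.63e-10). Eno1, Aldoc and Pkm, encoding an enolase, an aldolase and pyruvate kinase, were 1.90, 2.09 and 1.63-fold lower. The members that rose, named after their values were seen, were Pfkfb3 and Pfkfb4 (log2 fold change 0.25 for each), which encode enzymes that make an activator of glycolysis. Pfkfb4 did not pass when WT 1, WT 2, KO 2 or KO 3 was left out (0.25, 0.24, 0.23 and 0.21) or with the GC and length offset (0.16).

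Hypoxia-response genes showed the same direction. Of 29 tested, 20 fell and 2 rose (21 and 2 adjusted over the list alone), with a median log2 fold change of -0.73 (camera adjusted p = 3.53e-10; adjusted p = 0.262 with an estimated correlation). The glucose transporter gene Slc2a1, which is also on the glycolysis list, was 2.17-fold lower. Ero1l, for an endoplasmic reticulum oxidase, was 2.35-fold lower, Selenbp1 2.17-fold lower and the prolyl hydroxylase gene Egln3 2.42-fold lower. Bnip3, encoding a mitophagy receptor and chosen after its values were seen, was lower by a log2 fold change of -1.57 ± 0.10. Members outside the naming rule that went otherwise, chosen after their values were seen, were Hilpda (0.34 ± 0.08) and Ddit4 (0.25 ± 0.09), which rose, and Vegfa, encoding an angiogenic growth factor, which had 172 ± 3.95 CPM in WT and 175 ± 26.6 CPM in KO (SD; edgeR adjusted p = 0.853). Ddit4 did not pass when WT 1, WT 2, WT 3, KO 1 or KO 3 was left out, between 0.16 and 0.30, nor with the DESeq2 Wald test (0.26), limma-voom (0.25) or the GC and length offset (0.22), nor without WT 2 and KO 1 (0.13). Of 14 genes associated with HIF-2, 6 fell and 3 rose (6 and 3 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.291). Arg1, encoding arginase, was 2.10-fold lower and the iron exporter gene Slc40a1 1.65-fold lower, whereas Kdr, for a VEGF receptor, was 2.78-fold higher and Il6 2.31-fold higher.

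**Figure D2:**
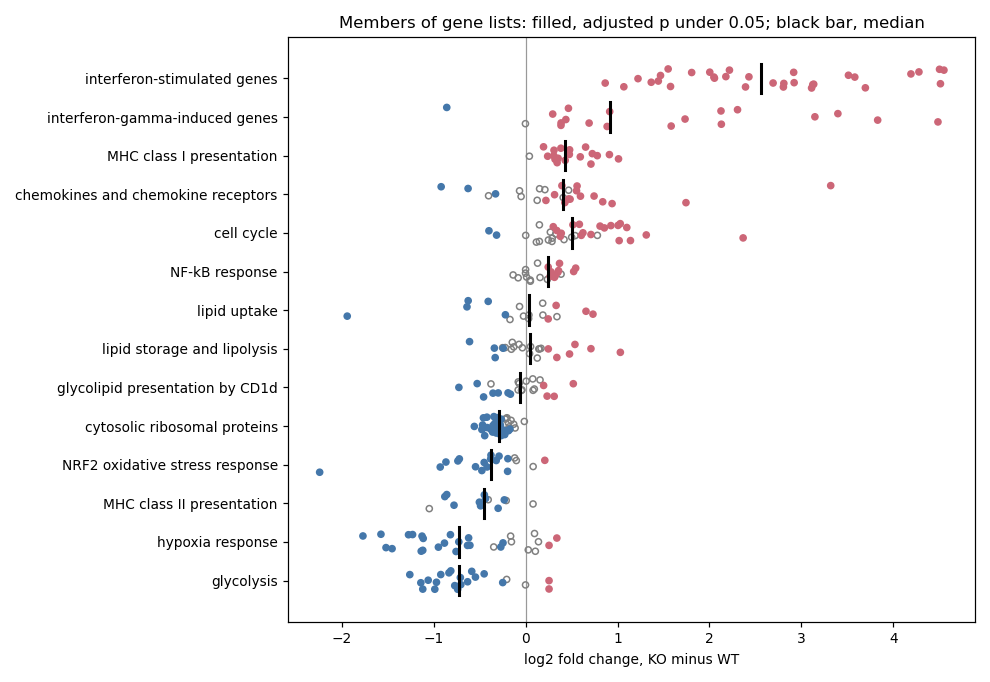
Log2 fold change, KO minus WT (x axis), of each tested member of 14 gene lists (rows); filled points had an adjusted p under 0.05 (red higher, blue lower), open points did not, and black bars are medians. All 32 interferon-stimulated genes lie above 0, and the medians of the glycolysis and hypoxia lists lie at -0.72 and -0.73.

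Interferon-stimulated genes rose without exception among the 32 tested, over all genes and adjusted over the list alone (32 of 32). Their median log2 fold change was 2.56, a 5.90-fold rise (camera adjusted p = 1.49e-32; adjusted p = 0.165 with an estimated correlation). Irf7, encoding a transcription factor of the interferon response (chromosome 7, 141262706 to 141266481, minus strand), went from 23.8 ± 6.36 to 464 ± 37.3 CPM (SD; edgeR adjusted p = 3.63e-10). Oasl2, Oas1g and Oas1a, of the oligoadenylate synthetase family, were 8.72, 7.01 and 4.01-fold higher. Among interferon-γ-induced genes, 17 rose and 1 fell of 19 (17 and 1 adjusted over the list alone; camera adjusted p = 1.33e-10; adjusted p = 0.146 with an estimated correlation). The GTPase genes Irgm1, Igtp and Ifi47 were 4.94, 4.38 and 8.86-fold higher, and the member that fell was Ciita. The macrophage, plasmacytoid dendritic cell and mast cell and basophil marker lists also passed upwards (camera adjusted p = 0.0133, 0.0313 and 0.00292; adjusted p = 0.46, 0.262 and 0.262 with an estimated correlation), with 7 higher and 3 lower of 16, 2 and 0 of 6, and 4 and 0 of 7. Several interferon-induced genes have near-identical copies, among them Ifit3 and Ifit3b, the Oas1 genes, Tgtp2 and the p200 family, and Igtp overlaps Irgm2 on the same strand. Their single values are uncertain where reads could be split between copies. Ifnb1, the interferon-β gene, and Ifng were looked at after their values were seen. Reads of Ifnb1 numbered 1, 0 and 0 in WT and 4, 11 and 12 in KO, too few to pass the count filter. With no low-count filter its log2 fold change was 4.21 (edgeR adjusted p = 0.00188), a fitted value that depends on the prior count. Adjusted p-values of that fit are not comparable with the others. For Epas1, at a log2 fold change of -0.97, the edgeR adjusted p was 1.15e-14 there against 3.45e-05 in the main fit. Ifng had 1 read over all libraries.

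Antigen presentation genes of the MHC classes moved in opposite directions. Of 19 MHC class I genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.43 (camera adjusted p = 2.11e-10; adjusted p = 0.146 with an estimated correlation). The peptide transporter gene Tap1 was 2.01-fold higher, Tapbp 1.64-fold, H2-K1 1.51-fold and H2-D1 1.28-fold. Of 13 MHC class II genes, 9 fell and 0 rose (10 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 2.04e-05; adjusted p = 0.146 with an estimated correlation). Ciita, the class II transactivator, was 1.81-fold lower, H2-DMb2 1.84-fold, H2-Eb2 1.72-fold and H2-Ab1 1.41-fold, the last from 1428 to 1016 CPM. H2 genes resemble each other, Tap1 overlaps Psmb9 and Tapbp overlaps Zbtb22, so single values of these genes are uncertain. With scaling to library size only or the GC and length offset, 1 class II gene rose.

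Genes of costimulation and dendritic cell maturation rose in 10 and fell in 3 of 20 cases (11 and 3 adjusted over the list alone; camera adjusted p = 0.0317; adjusted p = 0.627 with an estimated correlation). Tnfsf4 (OX40 ligand) was 1.89-fold higher, and Ccr7, Cd86 and Cd40 were 1.47, 1.44 and 1.47-fold higher. The list did not pass without WT 3 (median 0.22), without KO 1 (0.17) or without WT 2 and KO 1 (0.17). Chemokine and chemokine receptor genes rose in 14 and fell in 3 of 25 cases (16 and 3 adjusted over the list alone; camera adjusted p = 0.000771; adjusted p = 0.165 with an estimated correlation). Cxcl10, itself interferon-inducible, was 9.98-fold higher, and Ccl9 1.79-fold, whereas Cx3cr1 was 1.54-fold lower. NF-κB response genes rose in 10 and fell in 0 of 21 cases (10 and 0 adjusted over the list alone; camera adjusted p = 0.00205; adjusted p = 0.46 with an estimated correlation), by 1.46-fold for Rel and 1.28-fold for Nfkb2, and 1 fell without KO 1, without WT 2 and KO 1 or with the GC and length offset. Of 17 cytokine genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), without the list passing (camera adjusted p = 0.059). It passed without WT 1, WT 2 or KO 2 (median 0.22, 0.22 and 0.04), with no low-count filter (0.18), with the replicate number as a block (0.16) and with the GC and length offset (0.21), where 1 gene fell. Il1b was 3.47-fold higher, Il6 2.31-fold, Osm 1.60-fold and Il1rn 1.35-fold. Tnf (log2 fold change -0.005 ± 0.08) and Il12b (-0.03 ± 0.08), chosen after their values were seen, did not pass the test. Of 13 genes of alternative activation, 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0843), with Chil3 1.60-fold and Fcgr2b 1.46-fold lower and Pdcd1lg2 1.39-fold higher. That list passed with no low-count filter (median -0.22), and 1 gene rose when WT 1, WT 2, KO 1 or KO 3 was left out.

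The series names CD36-mediated lipid accumulation in its title. Cd36, encoding a fatty acid and lipoprotein receptor (chromosome 5, 17781690 to 17888801, minus strand), had 600 ± 5.70 CPM in WT and 682 ± 89.9 CPM in KO (SD). Every KO library lay above every WT library, but the log2 fold change of 0.18 ± 0.08, or 1.14-fold, did not pass (edgeR adjusted p = 0.11). KO 2 carried much of it, and without that library the log2 fold change was 0.07. It passed without KO 1 (0.26), without WT 2 and KO 1 (0.27), with no low-count filter (0.20) and with the GC and length offset (0.25). Adjusted p-values with no low-count filter ran far lower at similar fold changes, so that pass is not comparable with the others. Lipid uptake genes as a group went both ways, with 4 higher and 5 lower of 17 (5 and 6 adjusted over the list alone; camera adjusted p = 0.996; the median of 0.03 and the mean of -0.08 differ in sign). The median was 0.10 without WT 3 and negative without WT 1, WT 2, KO 2 or KO 3. Fabp4, Lpl and Vldlr, for a fatty-acid-binding protein, lipoprotein lipase and the VLDL receptor, were 1.56, 1.54 and 3.84-fold lower, and the fatty acid transporter gene Slc27a1 was 1.26-fold higher.

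Lipid storage and lipolysis genes rose in 6 and fell in 4 of 23 cases (6 and 4 adjusted over the list alone; camera adjusted p = 0.805). Plin2, encoding the lipid droplet coat protein perilipin 2 (chromosome 4, 86648386 to 86670060, minus strand), was 1.39-fold higher, from 1314 ± 29.5 to 1829 ± 52.4 CPM (SD; edgeR adjusted p = 5.83e-06). The triglyceride synthesis gene Dgat1 was 1.64-fold and the hormone-sensitive lipase gene Lipe 1.45-fold higher, and the monoglyceride lipase gene Mgll was 1.53-fold lower. Dgat2 and Hilpda, chosen after their values were seen, rose by log2 fold changes of 1.03 ± 0.21 and 0.34 ± 0.08. Of 21 fatty acid oxidation genes 6 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.291), among them Ppard 1.505-fold and Hadhb 1.27-fold lower and the carnitine carrier gene Slc25a20 1.38-fold higher. The number that fell was 2 without WT 2 or without WT 2 and KO 1, and 3 without WT 1, WT 3 or KO 3 or with scaling to library size only. Of 14 fatty acid synthesis genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.967), with Elovl6 1.76-fold higher and Scd2 1.27-fold lower, and 1 rose without WT 1, WT 2, KO 2 or KO 3. Of 24 cholesterol synthesis genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.547), with Sqle 1.26-fold lower and Pmvk 1.61-fold higher. Of these, 1 rose and 2 fell without KO 3, and 2 rose without WT 2 or with the GC and length offset. Targets of the lipid-sensing receptors LXR and PPAR-γ rose in 4 and fell in 1 of 14 cases (5 and 1 adjusted over the list alone; camera adjusted p = 0.0475; adjusted p = 0.46 with an estimated correlation). Tgm2 was 1.73-fold, Nr1h3, encoding LXRα, 1.41-fold and Pltp 1.37-fold higher. That list did not pass when WT 1, WT 2, KO 2 or KO 3 was left out, where its median ran from 0.12 to 0.14, nor with at least 10 counts in every library of a group (0.14), the replicate number as a block (0.13) or the GC and length offset (0.09).

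**Figure D3:**
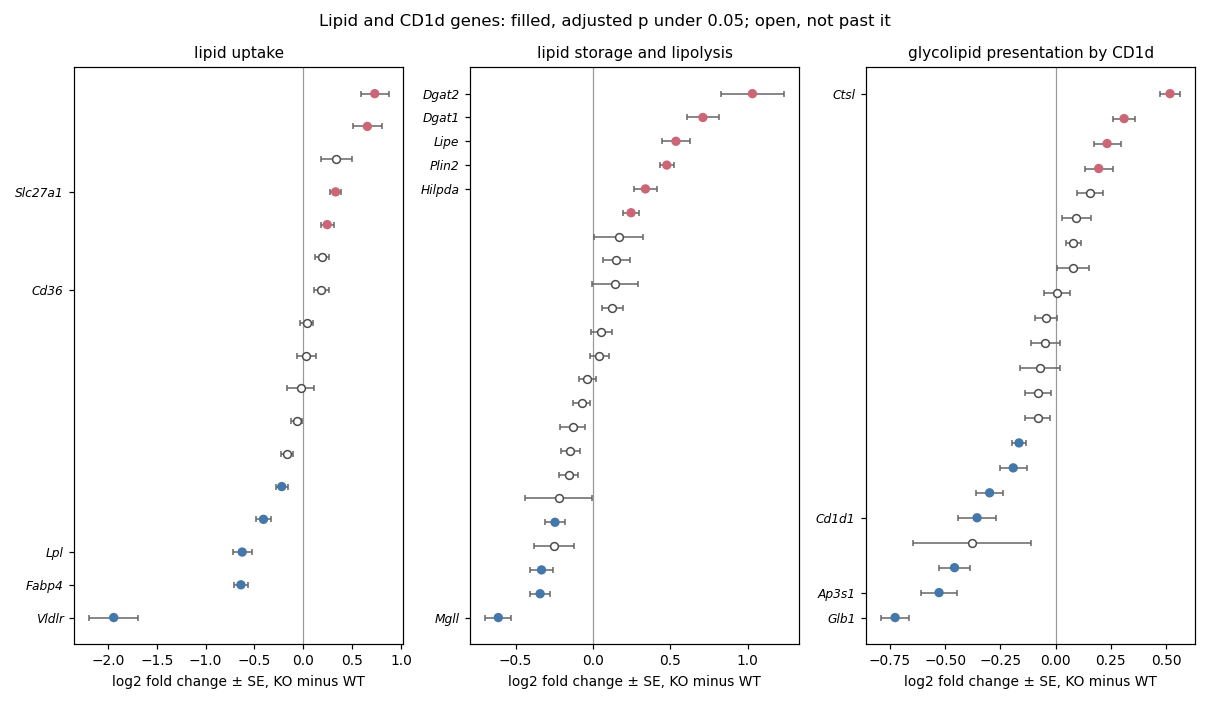
Log2 fold change, KO minus WT (x axes), of the tested members of 3 gene lists with the SE as bars; filled points had an adjusted p under 0.05 (red higher, blue lower) and open points did not, and the genes named in the text are labelled. In each list members lie on both sides of 0, with Cd36 open at 0.18, Plin2 filled at 0.48 and Cd1d1 filled at -0.36.

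Genes of glycolipid presentation by CD1d, the pathway that presents α-galactosylceramide, also went both ways. Of 22 tested, 7 fell and 4 rose (7 and 5 adjusted over the list alone; camera adjusted p = 0.483). The gene of the presenting molecule itself, Cd1d1, chosen after its values were seen, fell 1.28-fold (log2 fold change -0.36 ± 0.08, edgeR adjusted p = 0.0074), from 44.4 ± 1.69 to 34.7 ± 3.93 CPM (SD). It did not pass without KO 3 (-0.32, edgeR adjusted p = 0.0508, in a range of 0.000428 to 0.0508 over the alternatives). The lysosomal enzyme gene Glb1 was 1.66-fold lower, Ap3s1, of the AP-3 sorting adaptor, was 1.44-fold lower, and the protease gene Ctsl was 1.43-fold higher. Without WT 1, 2 genes of the list rose. Glb1 shares exon sequence with Tmppe on the same strand. Of 21 lysosome and phagocytosis genes 6 fell and 5 rose (8 and 6 adjusted over the list alone; camera adjusted p = 0.335; the median of -0.08 and the mean of 0.04 differ in sign). Ctsk, encoding cathepsin K, was 2.20-fold lower and the Fc receptor gene Fcgr1 7.77-fold higher.

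Genes of the NRF2 oxidative stress response fell in 15 and rose in 1 of 19 cases (15 and 1 adjusted over the list alone), with a median log2 fold change of -0.38 (camera adjusted p = 8.83e-08; adjusted p = 0.165 with an estimated correlation). Gsta3, encoding a glutathione transferase, was 4.73-fold lower, Gclm 1.91-fold, Cat, encoding catalase, 1.82-fold and Prdx1 1.67-fold. Without WT 1, KO 2 or KO 3, 0 rose. Of 14 iron handling genes 5 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.547), among them Slc40a1 1.65-fold, Hmox1 1.37-fold and the ferritin gene Fth1 1.15-fold lower, and Steap3 1.41-fold higher, and 2 rose without WT 2 or KO 2. Cytosolic ribosomal protein genes fell in 32 and rose in 0 of 43 cases (38 and 0 adjusted over the list alone), by a median log2 fold change of -0.29, or 1.22-fold (camera adjusted p = 3.53e-10; adjusted p = 0.46 with an estimated correlation). Rpl5, Rps4x, Rpl3 and Rpl10 were 1.47, 1.39, 1.39 and 1.34-fold lower. The number that fell was 21 without WT 1 or WT 2. Ribosomal protein genes have many pseudogene copies, and their single values are uncertain.

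Cell cycle genes rose in 19 and fell in 2 of 34 cases (23 and 2 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 6.71e-09; adjusted p = 0.146 with an estimated correlation). Top2a, encoding a topoisomerase of dividing cells, was 2.04-fold higher at 18.7 ± 1.56 CPM in KO (SD), and Rrm2 2.01-fold, whereas Pcna was 1.32-fold lower. Without KO 3, 12 rose, and without WT 1, WT 2 or KO 1, 1 fell. Immediate early and heat shock genes rose in 10 and fell in 3 of 22 cases (11 and 4 adjusted over the list alone; camera adjusted p = 0.0475; adjusted p = 0.454 with an estimated correlation), with Fos 2.43-fold, Nr4a2 1.92-fold and Dusp1 1.83-fold higher. That list did not pass when WT 3, KO 1 or KO 3 was left out, where its median ran from 0.20 to 0.24, nor with scaling to library size only (0.29) or the replicate number as a block (0.255), and 5 of its genes fell without WT 2 and KO 1. Of 25 genes of the unfolded protein and integrated stress response 6 rose and 4 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.483), with Ddit3 1.44-fold higher and Atf3 1.35-fold lower, and 2 fell without WT 1. Of 46 nuclear genes of the respiratory chain 2 rose and 4 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.417), with Uqcrfs1 1.29-fold lower. The list passed without WT 3 (median -0.09), where 8 fell and 0 rose, while 9 fell without KO 1 and 1 fell without WT 1, WT 2, KO 2 or KO 3. Of 11 mitochondrially encoded genes 5 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0843), mt-Co1 by 1.12-fold and mt-Nd6 by 1.32-fold, but 0 fell with the GC and length offset, where the median was 0.04. The list passed without WT 3 (-0.21), mt-Co1 did not pass without WT 2 and KO 1 (-0.15), and 3 genes fell without KO 3. Among members not called, chosen after their values were seen, mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 had 30.3, 12.6, 8.91 and 0.793 CPM in WT. They lay far below mt-Co1 at 11350 CPM, so these rows may not give the level of their transcripts.

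Of 6 lists of markers of cell types that such cultures can hold, those of macrophages, plasmacytoid dendritic cells and mast cells and basophils passed upwards and the other 3 did not pass. With an estimated correlation 0 of the 38 lists passed, and the lowest adjusted p was 0.146. Conventional dendritic cell markers rose in 5 and fell in 4 of 17 cases (5 and 4 adjusted over the list alone; camera adjusted p = 0.976; the median of -0.05 and the mean of 0.15 differ in sign), with Zbtb46 1.42-fold higher and Irf4 1.40-fold lower. Of these, 2 fell without WT 1 or KO 3 and 3 rose without WT 2. Macrophage markers rose in 7 and fell in 3 of 16 cases (7 and 4 adjusted over the list alone; camera adjusted p = 0.0133; adjusted p = 0.46 with an estimated correlation). Fcgr1 was 7.77-fold, Cd14 2.06-fold and Vcan 1.94-fold higher, and the lysozyme gene Lyz2 was 1.32-fold lower. Marco (log2 fold change 0.34), Adgre1 (0.12), Mrc1 (0.09), Csf1r (0.04), Cd68 (-0.13) and Mertk (-0.14), chosen after their values were seen, were not called. Monocyte markers rose in 6 and fell in 3 of 12 cases (6 and 3 adjusted over the list alone; camera adjusted p = 0.0915), with Ly6c2 2.40-fold higher and F13a1 5.67-fold lower. The list passed with no low-count filter (median 0.39) and without WT 2 and KO 1 (0.50). Plasmacytoid dendritic cell markers rose in 2 and fell in 0 of 6 cases (2 and 0 adjusted over the list alone; camera adjusted p = 0.0313; adjusted p = 0.262 with an estimated correlation). Bst2, which interferon also induces, was 2.39-fold and Tcf4 1.37-fold higher, while Siglech, chosen after its values were seen, had 0 to 2 reads in each library. Mast cell and basophil markers rose in 4 and fell in 0 of 7 cases (6 and 1 adjusted over the list alone; camera adjusted p = 0.00292; adjusted p = 0.262 with an estimated correlation), with Kit 1.51-fold and Gata2 1.85-fold higher and the basophil protease gene Mcpt8 at 1.15 CPM in KO, and 1 fell without KO 1. Neutrophil markers rose in 4 and fell in 2 of 11 cases (6 and 2 adjusted over the list alone; camera adjusted p = 0.0858), with Mmp9 3.08-fold higher and Mmp8 1.51-fold lower. The list passed without WT 2 (median 0.58), with no low-count filter (0.42) and with the GC and length offset (0.52).

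Other cell types were represented by few tested markers. Of 5 megakaryocyte and platelet markers 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.464), with Pf4 1.28-fold lower, and 0 rose without WT 2, WT 3 or KO 3. Of 5 markers of T, NKT and NK cells 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.483). It was Klrk1, 1.31-fold higher, which did not pass when WT 1, WT 3 or KO 2 was left out (log2 fold change 0.40, 0.29 and 0.34). Lists with fewer than 5 tested members were not tested as lists. Of 4 eosinophil markers 2 fell and 1 rose (2 and 1 adjusted over the list alone), with Ear2 1.72-fold lower. Of these, 0 rose whichever library was left out, and 1 fell without WT 2. Of 4 B cell markers 1 fell and 0 rose (1 and 0 adjusted over the list alone), namely Ighm at 2.29-fold lower, and 1 rose without WT 3. Of 3 stromal markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), with 0 falling without WT 1, WT 2 or KO 3 and 2 rising without WT 2. The erythroid marker Car2 had a log2 fold change of -0.13 ± 0.08 (edgeR adjusted p = 0.293). Of 4 sex-linked genes 2 fell and 0 rose (2 and 0 adjusted over the list alone), with Eif2s3y 1.27-fold lower, and 1 fell without WT 1, WT 3, KO 1 or KO 3. All 6 libraries held reads of the Y-linked gene Ddx3y, 865 to 1066, and at most 5 of Xist, which was chosen after its values were seen. Genes at the targeted and the driver locus were checked as well. Of 8 neighbours of Epas1 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.547), with Ttc7 1.22-fold higher and Calm2, Rhoq and Cript 1.24, 1.26 and 1.19-fold lower. Cript did not pass without WT 1 (-0.21), KO 3 (-0.25) or WT 2 and KO 1 (-0.22), or with the GC and length offset (-0.16), and 1 neighbour rose without WT 1, WT 2 or KO 3. Of 10 genes at the locus of Itgax, whose promoter drives CD11c-Cre, with Itgax itself among them, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.547; the median of -0.02 and the mean of 0.06 differ in sign), while 2 rose without WT 1 or KO 1 and 1 fell without KO 2. The median was 0.089 without WT 2 and also positive without WT 3, KO 1 or KO 3.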

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

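Leaving out WT 2 and KO 1, and the GC and length offset, were chosen after seeing the data. The other alternatives were planned. Of the 185 named genes besides Epas1 and Cd36, 160 kept their direction and side of the adjusted p threshold under the 16 alternatives run for single genes, which leave out the 2-fold minimum. Of the 38 tested lists 29 kept their call under 14 alternatives, fewer than the 16 above, so not every fit was run for lists. The 14 also leave out fry and camera with an estimated correlation, and with the latter each of the 17 lists that had passed lost its call. Calls of named genes were lost in 79 cases, most often without KO 3. Under those 14, lists lost a call in 15 cases and gained one in 14, and 0 were counted as reversed. The medians of some lists changed sign all the same. With the GC and length offset the median went from 0.03 to -0.07 for lipid uptake and from 0.04 to -0.03 for fatty acid synthesis. For mitochondrially encoded genes it went from -0.16 to 0.04. Direction reversed in 14 cases, all in genes near 0 that were called under none of these settings. When 1 library was left out, Vegfa ran from -0.104 to 0.092, Tnf from -0.045 to 0.032, Il12b from -0.1 to 0.036 and Aim2 from -0.018 to 0.079. Without WT 2 and KO 1, Vegfa was -0.088 and Tnf 0.043. Tnf was also 0.029 with library size only, 0.008 with no low-count filter and 0.021 with the GC and length offset, where Il12b was 0.002. The cause was not tested. Epas1 stayed past the adjusted p threshold under the 16 alternatives, between -0.86 and -1.08, but at 1.98-fold it lay below the 2-fold minimum.

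Calls numbered 1826 higher and 1586 lower. With a 2-fold minimum they were 301 and 183, by construction of the threshold. Leaving out each library in turn gave 1195 to 1971 higher and 975 to 1625 lower, the lowest without KO 3 and the highest without KO 1, with fewer libraries in each fit, and 62.6% of the calls were kept without KO 3. The DESeq2 Wald test made 1687 and 1380 calls, without WT 2 and KO 1 there were 1636 and 1336, and with the GC and length offset 1675 and 1800. Cd36 had a log2 fold change of 0.197 with no low-count filter and 0.267 without WT 2 and KO 1. With the GC and length offset it was 0.247. Cd36 passed the threshold in each, though adjusted p-values with no low-count filter are not comparable with the others. When 1 library was left out, its log2 fold change ran from 0.074 to 0.259. The cause was not tested. Its adjusted p ran from 0.0153 to 0.471. Of the 38 lists, 17 passed, against 0 with an estimated correlation, where the lowest adjusted p was 0.146. Fry found 25 with members moving on balance one way and 37 with members moving in either direction, a different question from that of camera.

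No pairing of libraries by replicate number was detected, and the labels do not say whether the numbers pair them. Deviations from the genotype means of libraries with the same number correlated at 0.015, -0.11 and 0.08, and 1 of 6 libraries correlated best with its own number. With the number as a block, calls were 1741 and 1506, and 16 lists passed, without the LXR and PPAR-γ targets (median 0.134) and the immediate early genes (0.255) but with the cytokines (0.159). Depth was not varied in the simulations. At the real library sizes, 22% of genes given the smallest simulated change were called with gene-specific dispersions, and 26.8% with dispersions on the mean trend. That change is larger than that of Cd36. The shares pool genes of all levels, so they do not say how often a gene as abundant as Cd36 would be called.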

Other observations

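The tests in this part were chosen after the results had been seen, as were the gene families. The genes named were too, apart from Ms4a4c, Egln3, Fcgr1, Fcgr2b and Pgk1, and the lists of interferon-stimulated, glycolysis, hypoxia and ribosomal protein genes were fixed beforehand. In all, 9 families were looked at, picked because members stood out, so counts are given without a test. Of 12 tested genes of the interferon-inducible p200 family, which lie between 173350879 and 174031810 on chromosome 1, 11 rose and 0 fell, and Aim2 had a log2 fold change of 0.03. Of 7 Schlafen genes 7 rose, Slfn4 by 3.35 and Slfn1 by 3.05 on the log2 scale. Among membrane-spanning 4A genes 7 of 9 rose, Ms4a4c by 4.57 and Ms4a6b by 3.01, and 0 fell. Of 12 Toll-like receptor genes 8 rose and 0 fell, with Tlr3 at 1.35 and Tlr9 at 0.67, of 4 Ly6 genes 4 rose, and of 12 PARP genes 6 rose and 0 fell. Other families went both ways, with 3 higher and 4 lower of 11 matrix metalloproteinase genes and 2 higher and 4 lower of 12 cathepsin genes. Of 4 Fc gamma receptor genes, Fcgr1 and Fcgr4 rose by 2.96 and 1.16 while Fcgr2b and Fcgr3 fell by 0.55 and 0.45. Members of a family resemble each other in sequence, so single values are uncertain.

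The macrophage elastase gene Mmp12 went from 7391 ± 159 to 3494 ± 624 CPM (SD, n = 3 each), 2.12-fold lower, and the thrombospondin gene Thbs1 from 922 to 2994 CPM. Within the oxygen-sensing pathway Egln1 and Egln3 fell by 0.73 and 1.27 and Vhl fell by 0.23 on the log2 scale, while Arnt (0.05 ± 0.06) and Hif1an (0.07 ± 0.07) did not pass. Stat2 and Irf9, which encode transcription factors of interferon signalling, rose by 2.05 and 1.22.

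Of 119 list genes with too few reads to pass the count filter, 4 had more reads in every KO library than in every WT library and an exact 95% interval of the ratio of depth-scaled reads above 1. Ifnb1 had 27 reads in KO against 1 in WT, a ratio of 24.8 (4.09 to 1020). Trf had 21 against 3, a ratio of 6.44 (1.92 to 33.7), and Cxcl9 11 against 1, a ratio of 10.1 (1.47 to 435). Ccl12 had 12 against 0, at least 3.68-fold higher with a floor of 3 counts over the group. These intervals cover counting error alone and were not adjusted for the number of genes looked at. Genes with fewer reads in every KO library were also looked for, by the same rule turned round, but their number is not given here. The 4 therefore do not show that such genes lean upwards. Counts of Rpl24, 0 to 5 reads in each library, and of Etfb, 0 to 8, were far below those of other members of their lists, and Gapdh at 349 CPM in WT lay below Pgk1 at 3027, so the level of a row in this table is not always the level of its transcript.

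The real split of the 6 libraries gave 3412 called genes, 1 of the 10 possible splits with so many, and the highest of the other splits gave 0. With 10 splits no share under 0.05 can be reached.

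The rise of interferon-stimulated genes was set against 2 technical explanations: without WT 2 and KO 1, the libraries with most scattered low-level reads, the median log2 fold change was 2.55 against 2.56, and with GC and length trends removed it was 2.49, with the list called in both. The tables argue against each as the whole cause. The median of the 30 members off chromosome 1, which holds the p200 cluster, was 2.75 ± 0.27 (bootstrap SE), but leaving out 2 of 32 members that had all risen could not have brought it under 2.41, so this test decides nothing. Bootstrap SEs, here and below, come from resampling member genes and leave out the spread between libraries. A strain-derived segment linked to the transgene, whose site is not given in the sources used here, and a shift in cell composition stay open. A difference between animals, culture or handling shared by the libraries of 1 genotype stays open too, untested, as does an effect of HIF-2α itself.

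The fall of glycolysis and hypoxia genes was set against 2. Over the 50 members of both lists the median was -0.72. It was -0.77 ± 0.08 (bootstrap SE) with GC and length trends removed and -0.70 ± 0.07 without WT 2 and KO 1, with both lists called each time, which argues against either as the whole cause. The hypothesis that loss of HIF-2α lowers these genes under DMOG may explain the fall, but a difference in cell composition, density or medium between the cultures stays open, and that hypothesis was not tested.

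The fall of cytosolic ribosomal protein genes may be technical, since these transcripts are short and have many copies. With GC and length trends removed the median was -0.28 ± 0.02 (bootstrap SE) against -0.29, and the list stayed called. The exon lengths used, such as 3920 bases for Rpl5 and 3175 for Rpl3, were not those of short transcripts. This fit therefore cannot decide whether short transcripts explain the fall. Had reads passed to pseudogene copies, the 176 ribosomal pseudogene rows would have gained reads, but their summed level was lower in every KO library than in every WT library (1534 CPM in WT, 1229 in KO, a log2 ratio of -0.32). The pseudogene reads argue against a passage of reads to those copies as the whole cause. An effect of transcript length stays open. A loss of reads with several alignments that differed between genotypes could not be examined in a table of counts and stays open too. So do a shift in cell composition and a lower share of ribosomal protein transcripts in KO cells.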
